A study of Drosophila melanogaster with 9 samples.

How the data were processed

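The series holds 9 RNA libraries from whole wandering final instar larvae kept on standard food at 25C, 3 each of the w118 wild type, larvae with 1 mutant Atg6 copy and larvae with 2. Total RNA was extracted with a Qiagen RNeasy kit and made into strand-specific Illumina libraries, for which the labels state paired reads of 75 bases. The deposited file gives FPKM (fragments per kilobase of transcript, scaled to library size) per gene and library. The submitters' processing notes name HISAT2 2.1.0, Cufflinks 2.2.1, limma and the genome build dm6; what each was used for beyond its name, and the annotation, are not given in the sources used here. Raw reads and counts were not used here.

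The table had 50244 lines for 15809 loci, each repeated 3 times per gene name with identical values. The planned analysis kept repeated lines as deposited; 1 line per locus was kept instead, since repeats would count the same measurement more than once, and the planned form was run as an alternative. Of the loci, 818 carried more than 1 gene name, so that values of those genes cannot be separated, 213 names occurred on more than 1 locus, and 1278 loci were at 0 in each library. Positions came from the BDGP6 annotation of Ensembl release 115 by symbol: 16243 of 16509 matched names lay within 5000 bases of the deposited locus, and 15362 loci had a position. Current symbols are given in parentheses where they differ.

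FPKM does not carry absolute depth, which is therefore unknown. The step between the smallest values of a library gave its depth relative to wild type 1, from 0.784 to 1.29. FPKM sums ran from 754677 to 1.09906e+06, and the 10 highest loci held 19.0 to 24.2% of the sum in wild types and heterozygotes and 10.8 to 16.7% in homozygotes. Median-of-ratios factors of the libraries ran from 0.989 to 1.01, so scaling by them, an alternative setting below, changed the values little. Correlations between libraries ran from 0.919 to 0.994, and no 2 libraries were duplicates.

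Loci with FPKM of at least 1 in at least 3 libraries were tested (10887). On log2(FPKM + 1), limma 3.58.1 (lmFit, contrasts.fit and eBayes with trend, in R 4.3.3) fitted the 3 genotypes together, with a spread shared by the 9 libraries. The contrasts were homozygote against wild type, heterozygote against wild type, homozygote against heterozygote and heterozygote against the mean of the other genotypes, with an F test of any difference. Benjamini-Hochberg adjustment was over the tested loci, at a threshold of 0.05. The pseudocount of 1 makes fold changes of genes near that level come out too small. P-values measure the spread between these libraries, and the labels do not say that they came from separate cultures or animals.

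Gene lists (43, with 1042 entries on 1024 loci) were written from general knowledge of the fly; 16 entries, mostly older proteasome names, matched no locus. The 42 lists with at least 3 tested loci were tested by camera with a preset correlation of 0.01, with camera on an estimated correlation, with camera on ranks, and with fry. Genes were named by a rule: Atg6, w and genes within 20 kb of Atg6; in each comparison the 10 largest rises and 10 largest falls among those past the threshold, with a mean of at least 5 FPKM in the higher genotype and no overlap between the libraries of the 2; and up to 3 genes per direction of each list with the smallest adjusted p or, with none past the threshold, the most abundant one. A choice of these is printed. Location was tested by Fisher exact tests per chromosome arm (adjusted over arms and comparisons) and within 1 Mb of Atg6. The samples, comparisons, tests, lists, naming rule and most alternative settings were set before the data were examined.

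On simulated data with 10887 loci, 200 of them changed between homozygote and wild type, the same steps called 72.0% of loci changed 2-fold and 89.0% of loci changed 4-fold. Of the calls 3.01% were unchanged loci, and the unchanged heterozygote had 0 calls. The changed loci were drawn from those at 5 FPKM or more in the wild type, and the noise of each locus was independent. Real loci vary together between libraries and many are weaker, so these shares need not hold for the data. The alternative settings were pseudocounts of 0.1 and 5, no filter, a filter at 5 FPKM, median-of-ratios scaling, quantile normalization, no trend, a robust fit, library weights, a fit of 2 genotypes at a time, a block for the replicate number, an adjusted p under 0.01, a 2-fold minimum, a distance of 5 Mb, the other list tests, and leaving out each library in turn. Added after the data were seen were the repeated lines as deposited, Lsp1beta set to missing in the 2 libraries where it was given as 0, loci with a single name, the muscle list score as a covariate, and 2 settings for the testis list, 1 without wild type 1 and 1 with the glue list score as a covariate, and for families of gene names both scalings and leaving out each library. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Tools that model raw counts were not used, since the file holds FPKM.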

Results

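Whole wandering final instar larvae with 2, 1 or 0 working copies of Atg6 were compared by RNA sequencing, with 3 libraries each of the wild type, the heterozygote and the homozygote. Atg6 is the fly Beclin 1, a subunit of the lipid kinase complex that starts autophagosome formation and acts in endosome traffic. Of 15809 loci, 10887 were tested, and levels are given as mean FPKM ± SD of the 3 libraries of a genotype. Changes are log2 fold changes of FPKM + 1 with their standard error (SE), a scale on which the changes of weakly expressed genes come out smaller than they are.

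Atg6 RNA followed the genotype in each library. Its FPKM was 16.1, 14.3 and 17.0 in the wild types, 7.58, 7.98 and 8.89 in the heterozygotes, and 0.0270, 0 and 0.0563 in the homozygotes. The log2 fold change against the wild type was −0.88 (SE 0.10, limma adjusted p = 0.0177) in the heterozygote and −4.03 (SE 0.10, adjusted p = 1.04e-06) in the homozygote, and −3.15 (adjusted p = 8.1e-06) from heterozygote to homozygote. The heterozygote call was lost without wild type 1, wild type 3, any of the 3 heterozygotes or homozygote 3 (adjusted p = 0.0540 to 0.140), with a pseudocount of 0.1 (0.207) and with only the 2 genotypes fitted (0.0762). Beside it, CG5991 (Pisd, a mitochondrial phosphatidylserine decarboxylase) rose from 12.01 ± 0.523 FPKM to 20.7 ± 0.933 in the heterozygote and 36.8 ± 3.27 in the homozygote, by 0.74 (SE 0.08, adjusted p = 0.0179) and 1.53 (SE 0.08, adjusted p = 6.29e-05). Its locus overlaps that of Atg6 in the annotation, so the values of the 2 loci cannot be fully separated. CG5986, also within 20 kb, rose from 36.4 ± 1.48 to 57.4 ± 0.886 and 83.7 ± 2.86 FPKM, by 0.65 (adjusted p = 0.0177) and 1.18 (adjusted p = 7.54e-05). The heterozygote calls of CG5991 and CG5986 were lost without any wild type, any heterozygote or homozygote 3 in turn (adjusted p = 0.0537 to 0.147), with only the 2 genotypes fitted (0.0623 and 0.0629) and for CG5986 after quantile normalization (0.154), whereas the homozygote calls of both held without each of the 9 libraries.

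The other genes within 20 kb of Atg6 changed less. In the homozygote Ime4 (Mettl3, an RNA methyltransferase) fell (log2 fold change −0.34, limma adjusted p = 0.0495) and Miro (a GTPase for mitochondrial transport) rose (0.45, adjusted p = 0.0449). The call of Ime4 held only without wild type 2, and that of Miro only without homozygote 2 or 3 (adjusted p up to 0.135 and 0.119 without another library). The loci spas, CG6000/CR44097, SMC1, KrT95D, Rox8, Hsp68 and 4EHP/Syx1A were not past the threshold in any of the 3 comparisons. The eye colour gene w, marker of the background, shares a locus with CG32795, so their values cannot be separated, and the labels do not say whether the mutant chromosome carries a further copy of w. That locus rose from 37.0 ± 10.6 to 71.6 ± 14.2 FPKM in the homozygote (0.95, SE 0.22, adjusted p = 0.0263). Without wild type 1, wild type 3, homozygote 1 or homozygote 3 it was not past the threshold (adjusted p = 0.0528 to 0.0866), and in the heterozygote it did not pass (64.6 ± 9.9 FPKM, 0.81, adjusted p = 0.489).

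**Figure D1:**
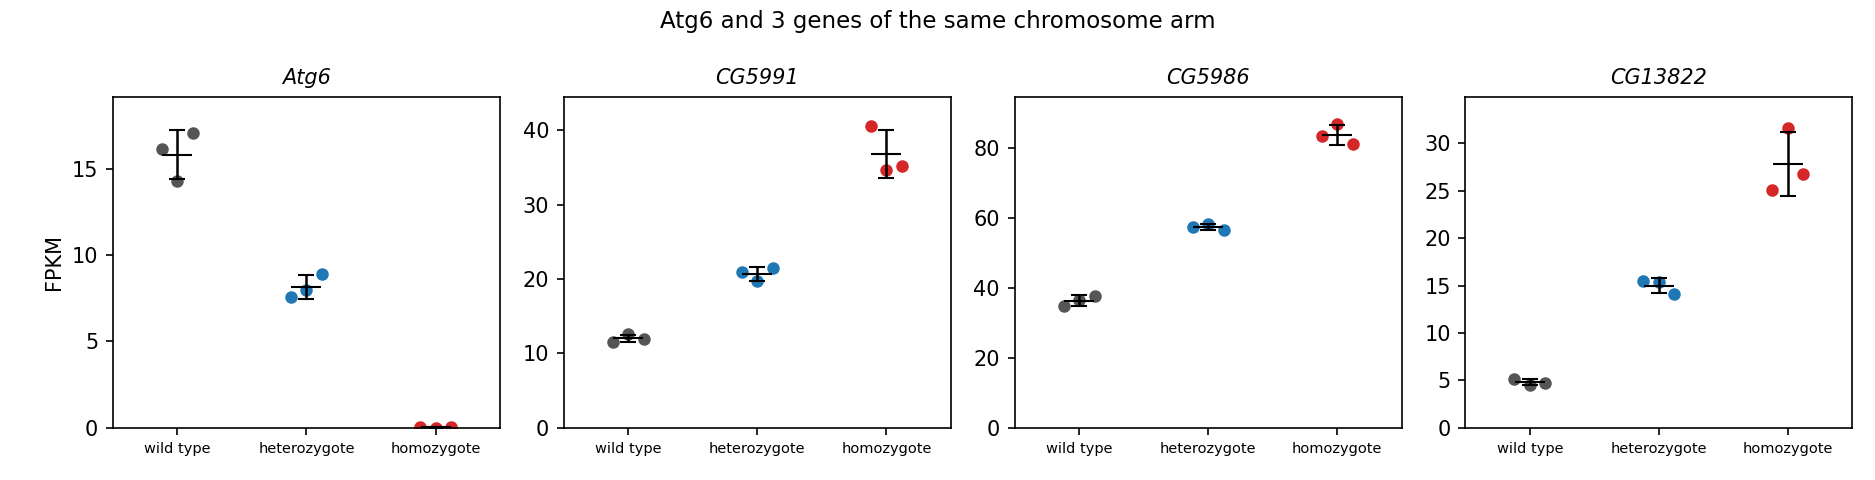
FPKM of Atg6, CG5991, CG5986 and CG13822 in each library (points), grouped as wild type, heterozygote and homozygote on a linear axis, with bars for mean ± SD of 3 libraries. Atg6 dropped from 15.8 to 8.15 and 0.0278 FPKM, while the other 3 genes climbed.

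How larvae without a working copy of Atg6 differed was asked first, homozygote against wild type with 3 libraries each. Variants of the mutant stock and larval stage could not be told apart from the loss of Atg6 in any of the 3 comparisons. Of the gene lists, the immune-induced secreted peptides of the bomanin and daisho families had the highest median rise (12 of 14 higher, median log2 fold change 4.63, limma camera adjusted p = 0.179 with an estimated correlation). IM3 (BomS3) went from 5.87 ± 4.3 to 706 ± 302 FPKM (6.77, SE 0.51, limma adjusted p = 0.000208). IM14 (Dso2) went from 1.11 ± 0.97 to 200 ± 72 FPKM (6.60, SE 0.42, adjusted p = 0.000105). Of 10 markers of lamellocytes, the large flat blood cells that encapsulate parasites, 8 rose. The integrin ItgalphaPS4 went from 1.95 ± 1.5 to 117.9 ± 12.53 FPKM (5.48, SE 0.39, adjusted p = 0.000183). Of 30 testis genes 12 fell, of 11 ecdysteroid synthesis genes 4, of 11 heat shock genes 5 (1 rose) and of 11 glue genes 2 (1 rose). These 4 lists were lower as sets by camera, with adjusted p = 0.635 for heat shock and 0.761 for the others with an estimated correlation. Of 86 cytoplasmic ribosomal protein genes 79 rose (median 0.67, adjusted p = 0.635 with an estimated correlation), but 0 after quantile normalization (median 0.24, 11 higher and 2 lower at an unadjusted p under 0.05 in limma). In all, 2396 of 10887 genes were past the threshold (22.0%; 1343 higher and 1053 lower), of which 397 rose and 696 fell by at least 2-fold, and 4478 had an unadjusted p under 0.05. With a pseudocount of 5 the calls were 1216 higher and 589 lower, and with a filter at 5 FPKM 1291 and 659. They were 583 higher and 143 lower without wild type 3, and 719 and 188 without homozygote 3. With only the 2 genotypes fitted they were 550 and 143, whereas without wild type 2 they were 1414 and 1674.

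Of 14 tested bomanin and daisho genes, 12 rose and 0 fell (13 and 0 when adjusted over the list alone), with a median log2 fold change of 4.63 and a mean of 4.36. The set moved up against the other genes (limma camera, adjusted p = 4.99e-10), with adjusted p = 0.179 with an estimated correlation between its genes. IM2 (BomS2; 6.27, SE 0.49), IM1 (BomS1; 5.84, SE 0.55), IM4 (Dso1; 6.19, SE 0.70) and CG15067 (BomBc2; 4.43, SE 0.33, adjusted p = 0.000211) were among those that rose. Of 16 classical antimicrobial peptides 0 passed in limma (0 rose and 3 fell at an unadjusted p under 0.05), their median was −0.31, and camera gave adjusted p = 0.581 (fry adjusted p = 0.850). Against each gene's mean over the 9 libraries, the median of that list was 0.94, −1.01 and 2.31 in the wild types and 0.21, 0.73 and −0.49 in the homozygotes. Its change was −1.55 without wild type 2 (camera adjusted p = 0.0424), but 0.53 without wild type 3 (adjusted p = 0.811) and 0.26 without homozygote 3 (adjusted p = 0.801). The antifungal peptide Drs was spread widely within genotypes, at 248 ± 264 FPKM in the wild type and 949 ± 546 in the homozygote (2.86, adjusted p = 0.124). CG14610 (5.93, SE 0.56) and CG9928 (5.64, SE 0.65), 2 genes of unknown function, and the long noncoding RNA CR44948 (5.97, SE 0.62) rose by a similar size.

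Some genes of the Imd and Toll pathway lists rose by smaller amounts. In the Imd and peptidoglycan recognition list 6 of 18 rose and 0 fell (6 and 0 over the list alone; median 0.20, limma camera adjusted p = 0.00174, and adjusted p = 0.179 with an estimated correlation). They included PGRP-LF, a decoy receptor that restrains the pathway (5.25 ± 0.63 to 15.4 ± 0.59 FPKM, 1.40, SE 0.10, adjusted p = 0.000208), and PGRP-LA (1.13, SE 0.11, adjusted p = 0.000895). The kinase gene ird5 (IKKbeta) rose by 0.73 (adjusted p = 0.00102), at a locus merged with CG10407 and CR45212 whose values cannot be separated. In the Toll pathway list 5 of 18 rose and 1 fell (6 and 1 alone). The receptor Tl (0.79, SE 0.08, adjusted p = 0.00104), the NF-kappaB factor dl (0.92, SE 0.13, adjusted p = 0.00454) and the ligand spz (14.7 ± 4.9 to 42.3 ± 7.7 FPKM, adjusted p = 0.00521) rose. The recognition protein PGRP-SD fell (−1.78, SE 0.26, adjusted p = 0.00475). That list as a set was not past the threshold (median 0.17, camera adjusted p = 0.0516, fry adjusted p = 0.0160), but passed without wild type 3, heterozygote 1, heterozygote 2 or homozygote 3, with a pseudocount of 0.1 and with no filter (adjusted p from 0.0184, and up to 0.432 under other settings). All of these genes kept their calls without each library in turn.

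Blood cell markers rose unevenly. In the lamellocyte list 8 of 10 rose and 0 fell (9 and 0 alone; median 1.24, mean 1.97, limma camera adjusted p = 4.87e-07, and adjusted p = 0.179 with an estimated correlation). With ItgalphaPS4 rose its partner, the integrin subunit mys (56.9 ± 3.9 to 173 ± 19 FPKM, 1.58, SE 0.11, adjusted p = 0.000168). So did the merged locus CG1208/glob3 (a sugar transporter relative and a globin, not separable; 4.80, SE 0.37, adjusted p = 0.000228). Of 13 plasmatocyte markers 5 rose and 1 fell (6 and 2 alone). He (hemese, a blood cell surface protein; 105 ± 11 to 404 ± 56 FPKM, 1.93, SE 0.17, adjusted p = 0.000574), the scavenger receptor Sr-CI (2.28, SE 0.25, adjusted p = 0.00125) and NimB5 (1.03, SE 0.14, adjusted p = 0.00332) rose. The locus CR45660/Pxn (peroxidasin, not separable from the noncoding RNA) fell (−0.82, adjusted p = 0.0334). The Pxn call was lost without any wild type, heterozygote 2, homozygote 1 or homozygote 3 (adjusted p up to 0.0955). As a set the plasmatocyte list was not past the threshold (median 0.54, camera adjusted p = 0.0534, fry adjusted p = 0.0196), but passed without wild type 2, heterozygote 1, heterozygote 2 or homozygote 3 and with no filter (adjusted p from 0.0229, and up to 0.193 under other settings). Of 5 crystal cell markers 0 passed in limma (0 at an unadjusted p under 0.05; median 0.23, camera adjusted p = 0.471, fry adjusted p = 0.278), with the prophenoloxidase PPO2 at 186 ± 100 and 196 ± 40 FPKM. Among 15 melanization genes 3 rose and 1 fell (4 and 1 alone; median 0.23, mean −0.01, adjusted p = 0.627), led by the lamellocyte phenoloxidase PPO3, at a locus shared with l(2)k09913 (0.84, SE 0.13, adjusted p = 0.00584). Of 8 lymph gland progenitor markers only dome rose (0.44, adjusted p = 0.0165, lost without wild type 3 or homozygote 3 with adjusted p up to 0.0654). That list had a median of −0.04 while camera leaned up (adjusted p = 0.982).

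**Figure D2:**
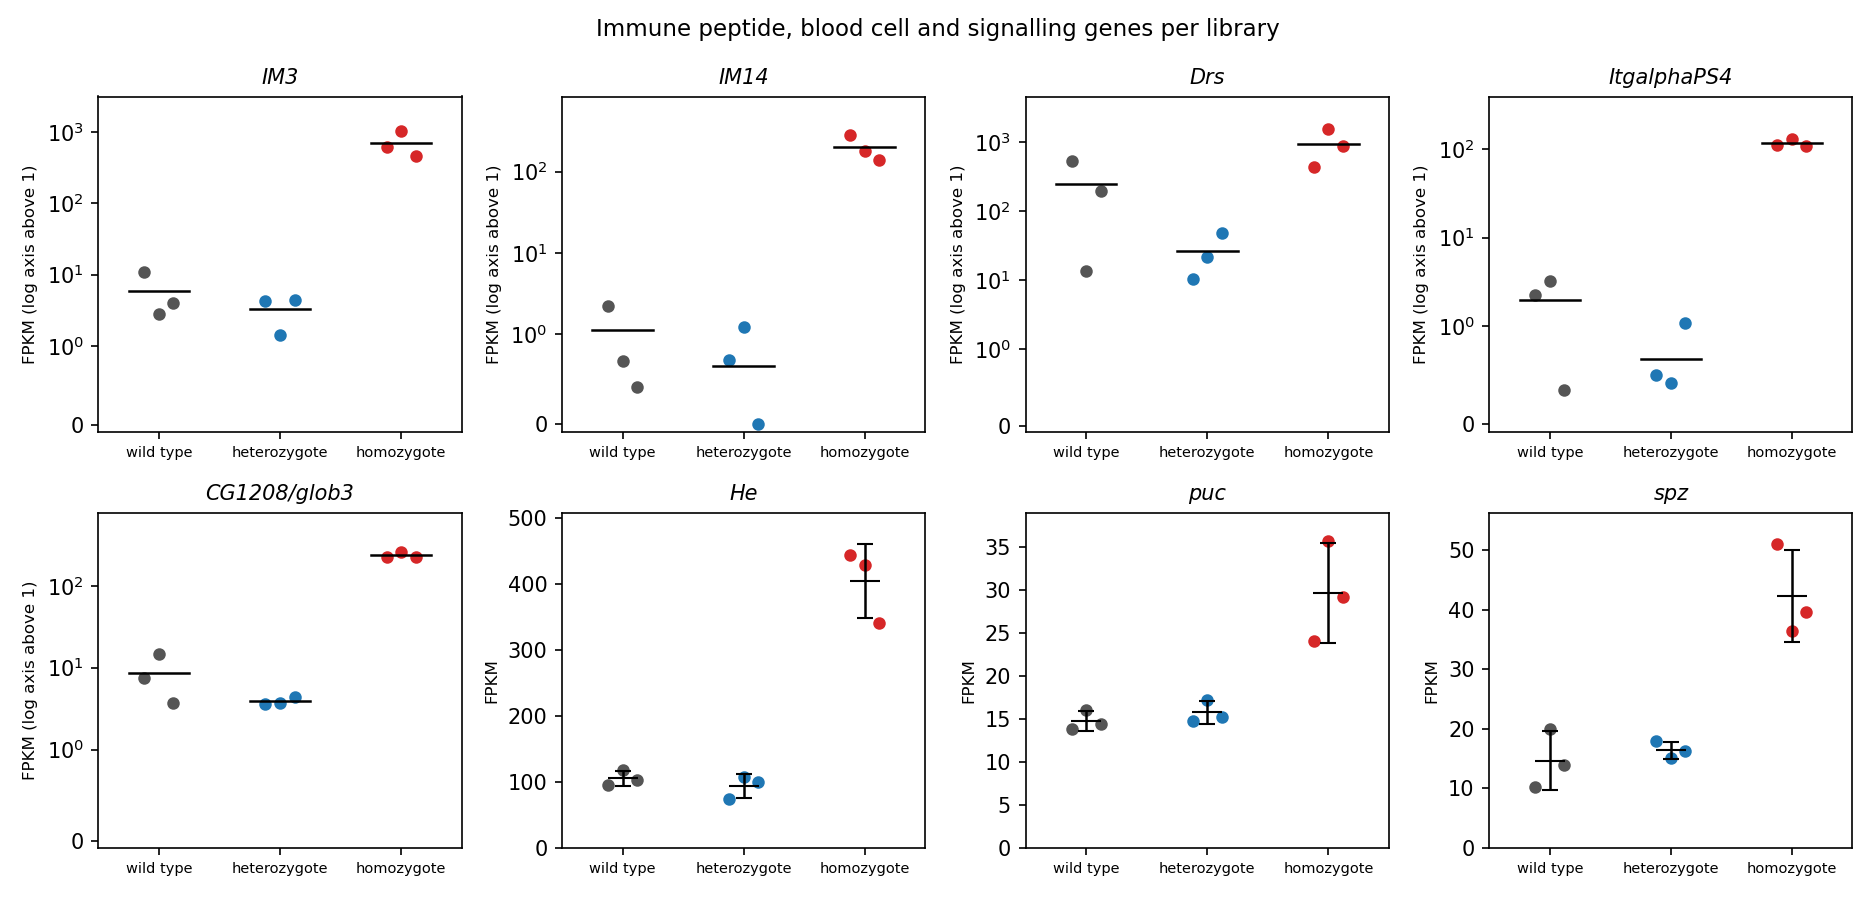
FPKM per library (points) of IM3, IM14, Drs, ItgalphaPS4 and CG1208/glob3 on log axes with a line at the mean, and of He, puc and spz on linear axes with mean ± SD, for 3 libraries of each genotype. IM3 averaged 5.87, 3.34 and 706 FPKM in wild type, heterozygote and homozygote, and Drs varied widely within the wild type (248 ± 264 FPKM).

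Genes of the JNK and JAK/STAT stress signalling lists rose as well. Of 15 JNK pathway genes 7 rose and 0 fell (9 and 0 alone; median 0.60, limma camera adjusted p = 0.000772, and adjusted p = 0.378 with an estimated correlation). They included both AP-1 subunits, kay (Fos; 42.04 ± 1.63 to 72.1 ± 5.97 FPKM, 0.76, SE 0.09, adjusted p = 0.00140) and Jra (Jun; 0.74, SE 0.11, adjusted p = 0.00409), and the feedback phosphatase puc (0.94, SE 0.14, adjusted p = 0.00503). Among 14 JAK/STAT genes 6 rose and 1 fell (9 and 1 alone; median 0.53, mean 0.84, camera adjusted p = 0.00321, and adjusted p = 0.179 with an estimated correlation). The stress peptides TotC (6.5 ± 1.1 to 71.5 ± 31 FPKM, 3.17, SE 0.36, adjusted p = 0.00150) and TotB (4.01, SE 0.63, adjusted p = 0.00587) rose. Their neighbour TotA fell from 1366 ± 28.5 to 442 ± 167 FPKM (−1.69, SE 0.28, adjusted p = 0.00704). A 4th member of that family outside the list, Victoria (TotE), rose by 6.06 (SE 1.00, adjusted p = 0.00719). Of 14 apoptosis genes 4 rose and 0 fell (7 and 0 alone; median 0.31, camera adjusted p = 0.0651, fry adjusted p = 0.0196; 0.0398 by camera without homozygote 1). They included the Bcl-2 family gene debcl (0.63, SE 0.10, adjusted p = 0.00719) and the TNF ligand egr (0.48, SE 0.09, adjusted p = 0.00957).

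Most cytoplasmic ribosomal protein genes rose by small amounts, except after quantile normalization. Of 86 cytoplasmic ribosomal protein genes 79 rose and 1 fell (80 and 1 alone; median 0.67, limma camera adjusted p = 3.09e-23, and adjusted p = 0.635 with an estimated correlation). Examples were RpLP2 (1721 ± 70.9 to 2951 ± 40.7 FPKM, 0.78, SE 0.11, adjusted p = 0.00452), RpS3 (0.86, SE 0.12, adjusted p = 0.00418) and RpL22, not separable from CR42491 (0.71, SE 0.10, adjusted p = 0.00432). Quantile normalization kept the direction (median 0.24, camera adjusted p = 0.00122) but left 0 of the 86 past the limma threshold, with 11 higher and 2 lower at an unadjusted p under 0.05. The paralog RpL10Aa fell (5.87 ± 3.3 to 1.51 ± 0.78 FPKM, −1.39, adjusted p = 0.0498), a call lost without wild type 1, wild type 3, heterozygote 2, heterozygote 3, homozygote 2 or homozygote 3 (adjusted p up to 0.147). Of 73 mitochondrial ribosomal protein genes 8 rose and 0 fell (4 and 0 alone; median 0.26, camera adjusted p = 6.27e-05, and adjusted p = 0.910 with an estimated correlation), led by mRpL39 (0.73, SE 0.12, adjusted p = 0.00722). Without homozygote 1 that set gave camera adjusted p = 0.0657. Against each gene's mean over the 9 libraries, its median was 0.51 in homozygote 1 but −0.10 and 0.08 in homozygotes 2 and 3. The wild types were at −0.09, −0.09 and −0.18.

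Some autophagy and endosome genes rose. Among 27 other autophagy genes 5 rose and 1 fell (5 and 1 alone; median 0.17, limma camera adjusted p = 0.103, fry adjusted p = 0.353). Without homozygote 1 that list passed (median 0.27, camera adjusted p = 0.0017), as it did with no filter (adjusted p = 0.0428), and without homozygote 2 its median was −0.05 (adjusted p = 0.936). The cargo receptor ref(2)P, the fly p62, rose from 133 ± 12 to 237 ± 31 FPKM (0.82, SE 0.12, adjusted p = 0.00398) and kept its call without each library. Atg101, merged with Pk17E (0.64, adjusted p = 0.0203), rose except without wild type 3 or homozygote 3 (adjusted p up to 0.0657), and the male germline paralog Atg8b fell (−1.73, adjusted p = 0.0464). The latter was lost without wild type 1, wild type 3, any heterozygote, homozygote 2 or homozygote 3 (adjusted p up to 0.139). In the endosome and vesicle list 8 of 25 rose and 0 fell (10 and 0 alone; median 0.20, camera adjusted p = 0.00223, adjusted p = 0.725 with an estimated correlation, and adjusted p = 0.401 after quantile normalization). One was the tethering subunit Vps33B (0.42, SE 0.08, adjusted p = 0.00974). Of 26 lysosomal genes 0 rose and 1, CG3376, fell (−0.94, adjusted p = 0.0406; 0 and 0 alone; median −0.11, camera adjusted p = 0.853). CG3376 lost its call without wild type 1, wild type 3, any heterozygote, homozygote 1 or homozygote 3 (adjusted p up to 0.126). Of 32 V-ATPase subunit genes 0 passed in limma (12 higher and 5 lower at an unadjusted p under 0.05; median 0.45, mean 0.06, camera adjusted p = 0.403, fry adjusted p = 0.434; camera adjusted p = 0.0104 with a filter at 5 FPKM). Vha16-1 was the most abundant (702 ± 170 and 1058 ± 269 FPKM).

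The largest fall was that of CG34026, a gene of unknown function, from 251 ± 67 to 0.0445 ± 0.077 FPKM (−7.89, SE 0.18, limma adjusted p = 1.04e-06). The glue protein gene CG7587 (Sgs5bis) fell from 2949 ± 783 to 189 ± 144 FPKM (−4.50, SE 0.80, adjusted p = 0.00974). Both held without each library in turn, as did the omega class glutathione transferase gene GstO3 (147 ± 6.7 to 14.2 ± 2.2 FPKM, −3.29, SE 0.11, adjusted p = 6.32e-06). Of 11 glue genes 1 rose and 2 fell (2 and 7 alone; median −2.11, mean −1.60, camera adjusted p = 0.0450, and adjusted p = 0.761 with an estimated correlation). Against each gene's mean over the 9 libraries, the glue median was −3.47 in homozygote 1 but −0.46 and −0.38 in homozygotes 2 and 3. In the wild types it was 0.44, 0.88 and 0.90. The glue set call was lost without wild type 2, wild type 3, heterozygote 1 or homozygote 2 and with no filter (camera adjusted p up to 0.128). Of 11 ecdysteroid synthesis genes 0 rose and 4 fell, among them the steroid hydroxylase genes dib (−1.16, SE 0.17, adjusted p = 0.00469) and phm (27.9 ± 4.4 to 11.02 ± 3.12 FPKM, −1.29, SE 0.22, adjusted p = 0.00887). The list (0 and 4 alone; median −0.56) was past the threshold as a set (camera adjusted p = 0.0450, and adjusted p = 0.761 with an estimated correlation), but not without wild type 2 or homozygote 1 (adjusted p up to 0.0758) or after quantile normalization (median −0.31, adjusted p = 0.103). Among 17 ecdysone response genes 1 rose and 2 fell (1 and 3 alone; median −0.46, camera adjusted p = 0.0651, fry adjusted p = 0.0426; from 0.00748 by camera without homozygote 2 or 3), with ImpE3 lowest in p (−2.37, SE 0.36, adjusted p = 0.00554). After quantile normalization the median of that list was −0.72, with 1 gene higher and 3 lower. Of the 2 tested Eig71E salivary peptide genes 0 passed in limma (2 lower at an unadjusted p under 0.05 and alone; median −2.07, too few for a set test). Eig71Ee was one of them (2803 ± 554 to 675 ± 562 FPKM, −2.70, adjusted p = 0.0554).

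Other large falls depended on which libraries were kept. The fat body protein Fbp1 (7199 ± 611 to 835 ± 792 FPKM, −4.44, limma adjusted p = 0.0496), the lipase locus CG6271/CG6277 (−3.81, adjusted p = 0.0377) and CG42500 (−3.58, adjusted p = 0.0357) fell. Their calls were lost without any wild type or any heterozygote (adjusted p up to 0.117). CG42716 (−3.42, adjusted p = 0.0389) and CG42798 (−3.36, adjusted p = 0.0422) fell as well. These were lost without wild type 1, wild type 3, heterozygote 2, heterozygote 3, homozygote 1 or homozygote 3, without wild type 2 for the former and without heterozygote 1 for the latter (adjusted p up to 0.117). The microRNA gene mir-4985 was at 22.6 ± 6.8 FPKM in the wild type and listed at 0 in the 3 homozygotes (adjusted p = 0.0255, and up to 0.0777 without wild type 1, wild type 3 or homozygote 3). Fbp1 was the 1 gene of 7 serum and storage protein genes that fell, and 0 rose (1 and 1 alone; median −0.47, camera adjusted p = 0.613). Lsp1beta of that list was given as 0 in heterozygote 3 and homozygote 1 but as 3299 or more in the other libraries.

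Testis genes and heat shock genes were lower as groups. Of 30 testis and male germline genes 0 rose and 12 fell (0 and 25 alone; median −1.43, mean −1.17, limma camera adjusted p = 4.87e-07, and adjusted p = 0.761 with an estimated correlation). They included sa, a testis transcription factor subunit (4.74 ± 1.9 to 1.07 ± 0.49 FPKM, −1.45, SE 0.31, adjusted p = 0.0183), and the sperm protein Mst84Dd (−1.71, SE 0.41, adjusted p = 0.0281). Of 41 proteasome genes 0 rose and 3 fell (0 and 0 alone, 11 lower at an unadjusted p under 0.05; median −0.41, camera adjusted p = 3.48e-05, and adjusted p = 0.800 with an estimated correlation). The proteasome median was −0.14 without homozygote 1 and −0.68 without homozygote 2, and against each gene's mean it was higher in homozygote 2 (0.35) than in the wild types (0.29, 0.10 and 0.27). All 3, Prosbeta4R1 (−1.13, adjusted p = 0.0337), Prosalpha6T (−1.50, adjusted p = 0.0394) and Prosbeta5R2 (−1.15, adjusted p = 0.0432), are testis forms. Of 11 heat shock genes 1 rose and 5 fell (1 and 7 alone; median −0.95, camera adjusted p = 0.0235, and adjusted p = 0.635 with an estimated correlation). The chaperones Hsp23 (931 ± 500 to 120 ± 95 FPKM, −3.07, SE 0.70, adjusted p = 0.0241) and Hsp67Bc (−1.93, SE 0.42, adjusted p = 0.0196) fell, and the co-chaperone stv rose (0.52, adjusted p = 0.0181). Without wild type 1, wild type 3 or homozygote 3 the calls of sa, Mst84Dd, Hsp23, Hsp67Bc and stv were lost (adjusted p = 0.0518 to 0.0928). The 3 proteasome genes were lost without these 3 and without heterozygote 2, heterozygote 3 or homozygote 2 (adjusted p up to 0.130), and Prosbeta5R2 also without heterozygote 1 or homozygote 1. Of 3 male dosage compensation genes 0 passed in limma (0 at an unadjusted p under 0.05; median 0.23, camera adjusted p = 0.948, fry adjusted p = 0.858), with roX1 at 124 ± 29 and 143 ± 7.7 FPKM.

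Detoxification, digestive and cuticle genes changed in both directions. Of 23 glutathione S-transferases D and E 4 rose and 1 fell (4 and 1 alone; median 0.26, limma camera adjusted p = 0.264, and 0.0295 without homozygote 2). GstD2 (10.9 ± 3.6 to 92.9 ± 25 FPKM, 2.99, SE 0.27, adjusted p = 0.000590) and GstE2 (1.21, SE 0.17, adjusted p = 0.00345) rose, and GstE14 fell (−0.77, adjusted p = 0.0242; 0.0839 without wild type 3). Of 24 cytochrome P450 genes 4 rose and 3 fell (5 and 3 alone; median 0.12, adjusted p = 0.636). Cyp12c1 rose (0.62, SE 0.10, adjusted p = 0.00755) and Cyp6g1, not separable from CG13175, fell (−1.49, SE 0.14, adjusted p = 0.000767). Of 19 Nrf2 and antioxidant genes 0 rose and 2 fell (0 and 2 alone; median 0.06 although camera leaned down, adjusted p = 0.978), led by CG6762 (Srx, sulfiredoxin; −1.82, SE 0.30, adjusted p = 0.00728). Of 45 digestive enzymes 3 rose and 4 fell (2 and 4 alone; median 0.05, adjusted p = 0.982). The maltases Mal-A8 (−3.21, SE 0.58, adjusted p = 0.00996) and Mal-A6 (−2.27, SE 0.44, adjusted p = 0.0139) and the protease Jon99Fi (1630 ± 309 to 412 ± 201 FPKM, −2.10, SE 0.36, adjusted p = 0.00838) fell. Of 65 cuticle proteins 4 rose and 6 fell (4 and 6 alone; median 0.08 although camera leaned down, adjusted p = 0.886). Cpr50Cb rose (1.08, SE 0.19, adjusted p = 0.00902) and Cpr12A fell (84.7 ± 21 to 17.4 ± 7.1 FPKM, −2.27, SE 0.33, adjusted p = 0.00432). The secreted protein gene yellow-d2 rose from 0.565 ± 0.16 to 198 ± 92 FPKM (6.85, SE 0.51, adjusted p = 0.000208), the largest rise of the comparison.

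Of 19 insulin and FOXO genes 4 rose and 1 fell (4 and 1 alone; median 0.13, limma camera adjusted p = 0.403). The growth kinase S6k rose (0.66, SE 0.13, adjusted p = 0.0133) and the stress gene Sesn fell (−0.85, SE 0.15, adjusted p = 0.0106). Of 14 ATF4 amino acid response genes 4 rose and 2 fell (5 and 3 alone; median 0.26, adjusted p = 0.627). Nmdmc (a folate enzyme of mitochondria; 1.91, SE 0.36, adjusted p = 0.0124, and 0.0530 without wild type 3) rose and CG3011 (Shmt, serine hydroxymethyltransferase; −0.70, SE 0.11, adjusted p = 0.00624) fell. The muscle list (19 genes, median 0.79, as in Act57B/snoRNA:660) and the oxidative phosphorylation list (18 genes, median 0.60, as in ATPsyn-beta) were past the threshold as sets (each camera adjusted p = 0.0450, and 0.910 with an estimated correlation). Of their genes 0 passed in limma, and 1 and 3 rose at an unadjusted p under 0.05. Against each gene's mean, the muscle median was 0.84, −0.55 and 0.60 in the homozygotes and −0.96, 0.39 and −0.70 in the wild types. For oxidative phosphorylation these were 1.08, −0.47 and 0.22, and −0.52, 0.10 and −0.52. Both set calls were lost without wild type 1, wild type 3 or homozygote 1 (adjusted p up to 0.264 and 0.563), and the muscle call without homozygote 3 as well. They were also lost with a filter at 5 FPKM (0.163 and 0.174), after quantile normalization (medians 0.45 and 0.34, adjusted p = 0.171 and 0.203) and, for oxidative phosphorylation, with median-of-ratios scaling (0.0536). Glycolysis (15 genes, 0 past in limma and 0 at an unadjusted p under 0.05; median 0.64, adjusted p = 0.0655, fry adjusted p = 0.413) was past the camera threshold without wild type 2 or homozygote 2 (adjusted p from 0.00142), as in Ald. Of 17 imaginal disc genes 0 rose and 2 fell (0 and 0 alone; median −0.34, adjusted p = 0.0450, and 0.910 with an estimated correlation; up to 0.115 without wild type 1, wild type 3, homozygote 1 or homozygote 3, 0.0542 with no filter, and 0.418 after quantile normalization with a median of −0.09). They were the eye and leg factor dac (−0.67, adjusted p = 0.0412) and eya (−0.53, adjusted p = 0.0489). Both calls were lost without wild type 1, wild type 3, heterozygote 2, heterozygote 3, homozygote 1 or homozygote 3, and eya also without heterozygote 1 or homozygote 2 (adjusted p up to 0.147).

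In the remaining lists few genes passed in limma. Of 23 lipid genes HLH106 (SREBP, the lipid synthesis regulator) rose (0.69, adjusted p = 0.0318) and yip2 (a thiolase) fell (−0.50, adjusted p = 0.0447; 0 and 0 alone; median −0.03, mean 0.14, camera adjusted p = 0.950). Of 28 cell cycle genes 2 rose and 1 fell (0 and 0 alone; median 0.02, mean −0.01, adjusted p = 0.886), with CDC45L (a replication helicase subunit) higher (0.35, adjusted p = 0.0276) and CycB3 lower (−0.54, adjusted p = 0.0408). Of 21 unfolded protein response genes crc (ATF4) rose (0.38, adjusted p = 0.0433) and Edem1 fell (−0.48, adjusted p = 0.0153; 0 and 1 alone; median −0.06, adjusted p = 0.831, and 0.00897 after quantile normalization). Of 7 Malpighian tubule genes 2 rose and 1 fell (2 and 2 alone; median −0.24, mean 0.08, adjusted p = 0.893), with Irk3, a potassium channel, higher (0.94, adjusted p = 0.0160). Of 17 nervous system genes Snap25 rose (0.72, adjusted p = 0.0405) and 0 fell (0 and 0 alone; median −0.04, mean 0.02, adjusted p = 0.982). Each gene named in this paragraph lost its call without wild type 3 or homozygote 3, and most also without another library (adjusted p = 0.0515 to 0.127).

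Across these 42 testable lists, 16 were past the threshold by camera (10 up and 6 down), 0 with an estimated correlation, and 13 by fry. Of the 16, 9 passed by fry, and testis and glue (each fry adjusted p = 0.0672), proteasome (0.171), imaginal disc (0.182), mitochondrial ribosomal (0.226), muscle (0.365) and oxidative phosphorylation lists (0.413) did not. The fry test asks whether the genes of a set move on balance 1 way, its mixed form whether they move in either direction, and neither compares them with other genes. Left out in turn, wild type 1, wild type 3, heterozygote 2, heterozygote 3 and homozygote 3 lowered the 2396 calls to 1035, 726, 1249, 1332 and 907, and leaving out wild type 2 gave 3088. Of the 10 largest rises 10 kept their call without each of the 9 libraries, and of the 10 largest falls 4 did.

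**Figure D3:**
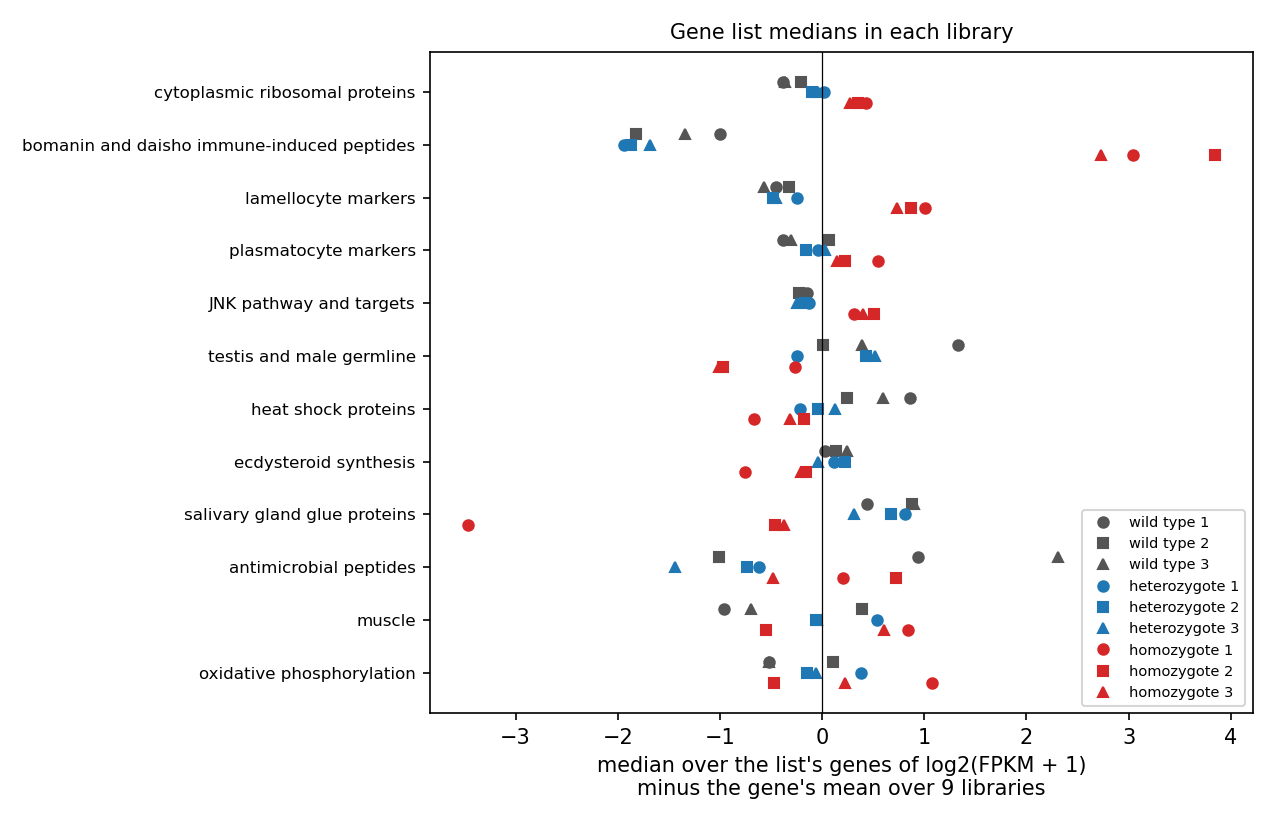
For 12 gene lists, the median over a list's genes of log2(FPKM + 1) minus the gene's mean over the 9 libraries, with 1 point per library coloured by wild type, heterozygote and homozygote. Bomanin and lamellocyte medians were high in the 3 homozygotes, while muscle medians differed as much within genotypes (−0.96 and 0.39 in wild types 1 and 2) as between them.

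Whether 1 lost copy of Atg6 was enough to change the larva was asked next, heterozygote against wild type with 3 libraries each. Very few genes changed: 23 of 10887 were past the limma threshold (16 higher and 7 lower, 17 of them at least 2-fold), with 622 at an unadjusted p under 0.05. The largest rise was yellow-d2, from 0.565 ± 0.16 to 106 ± 52 FPKM (log2 fold change 5.94, SE 0.51, adjusted p = 0.00467). CG34026 fell from 251 ± 67 to 60.4 ± 7.5 FPKM (−2.02, SE 0.18, adjusted p = 0.00628). None of the bomanin, lamellocyte or ribosomal protein genes that rose in the homozygote was past the threshold here.

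Several noncoding RNAs and genes of the X chromosome were among the 23. The hairpin RNA gene pncr009:3L rose from 4.45 ± 0.47 to 30.4 ± 2.6 FPKM (2.53, SE 0.11, limma adjusted p = 0.000221). The noncoding RNA CR42861 rose from 1.65 ± 0.49 to 12.2 ± 1.9 (2.32, SE 0.16, adjusted p = 0.00133), and CG32641 from 0.684 ± 0.17 to 8.37 ± 1.6 (2.47, SE 0.16, adjusted p = 0.00133). GstT3, a glutathione transferase gene of the X, rose from 13.7 ± 1.5 to 38.4 ± 1.7 (1.43, SE 0.11, adjusted p = 0.00256). CG13822 (GILT3, a thiol reductase relative 372 kb from Atg6) rose from 4.81 ± 0.34 to 15.0 ± 0.75 (1.46, SE 0.10, adjusted p = 0.00133). The 5 genes just given, yellow-d2 and CG34026 kept their calls without each library, but CG34026 was not past the threshold with a pseudocount of 0.1 (adjusted p = 0.107) or with only the 2 genotypes fitted (0.0655). CR40469 (3.29, SE 0.41, adjusted p = 0.0266), CG31226 (2.14, SE 0.26, adjusted p = 0.0266), the transporter Mrp4 (1.42, SE 0.16, adjusted p = 0.0179) and mago, of the exon junction complex (1.02, SE 0.10, adjusted p = 0.0130), rose. CG43221/CG43645 (2 genes not separable; −2.80, SE 0.39, adjusted p = 0.0490) and the X-linked CG4880 (−0.62, SE 0.09, adjusted p = 0.0490) fell. Calls of CG43221/CG43645 and CG4880 were lost without any of the 9 libraries (adjusted p up to 0.300). Those of mago were lost without wild type 1, wild type 3, heterozygote 1 or heterozygote 2, and those of Mrp4 also without heterozygote 3 or homozygote 3. Those of CR40469 and CG31226 were lost without 7 of 9 libraries (all but wild type 1 and homozygote 2 for CR40469, all but heterozygote 1 and homozygote 2 for CG31226; adjusted p up to 0.180). With only the 2 genotypes fitted mago, Mrp4, CR40469 and CG31226 did not pass (adjusted p = 0.0646 to 0.106), nor did CR40469 with a pseudocount of 0.1 (0.281).

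Of the 23, 11 lay among the 1744 tested genes of the X (odds ratio 4.83, 95% interval 1.93 to 11.98, Fisher exact p = 0.000358, adjusted p = 0.00322). The test counts genes as independent, although the loci of CG32640 and CG32641 on the X start at the same position. It was not repeated with a library left out. Within 1 Mb of Atg6 lay CG5991, CG5986 and CG13822 (odds ratio 7.05, 1.33 to 24.2, Fisher exact p = 0.0121), with no further call within 5 Mb (odds ratio 1.73, 0.328 to 5.9, Fisher exact p = 0.424). In the homozygote comparison the region within 1 Mb held no excess (odds ratio 1.05, Fisher exact p = 0.753), and chromosome 4 held few calls (6 of 86 genes, odds ratio 0.264, adjusted p = 0.00322). Of the 23 genes 22 were also past the limma threshold in the homozygote against the wild type, in the same direction (16 higher and 6 lower). CG43221/CG43645 was the exception. Independent lists would share 1.97 and 0.677 genes in those directions. Over all genes the 2 sets of fold changes had a correlation of 0.617 and a covariance of 0.195. In 100 simulations with no effect but shared wild types, each library was the gene mean plus a random sum of the 9 libraries' deviations from their genotype means. There the correlation had a median of 0.547 (−0.919 to 0.969) and the covariance a mean of 0.0600, a difference of 0.135 from the observed covariance. Of the 100 simulations 11 reached the observed covariance (highest 0.324) and 43 the observed correlation, so neither stood outside the simulated range. The simulated spread was that of all 3 genotypes, not of the wild types alone. In those simulations the shared calls had a median of 0 and a highest value of 337, and 1 simulation reached 22. With 3 wild types the controls could not be divided into groups of at least 2, so part or all of the excess may come from the shared libraries.

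**Figure D4:**
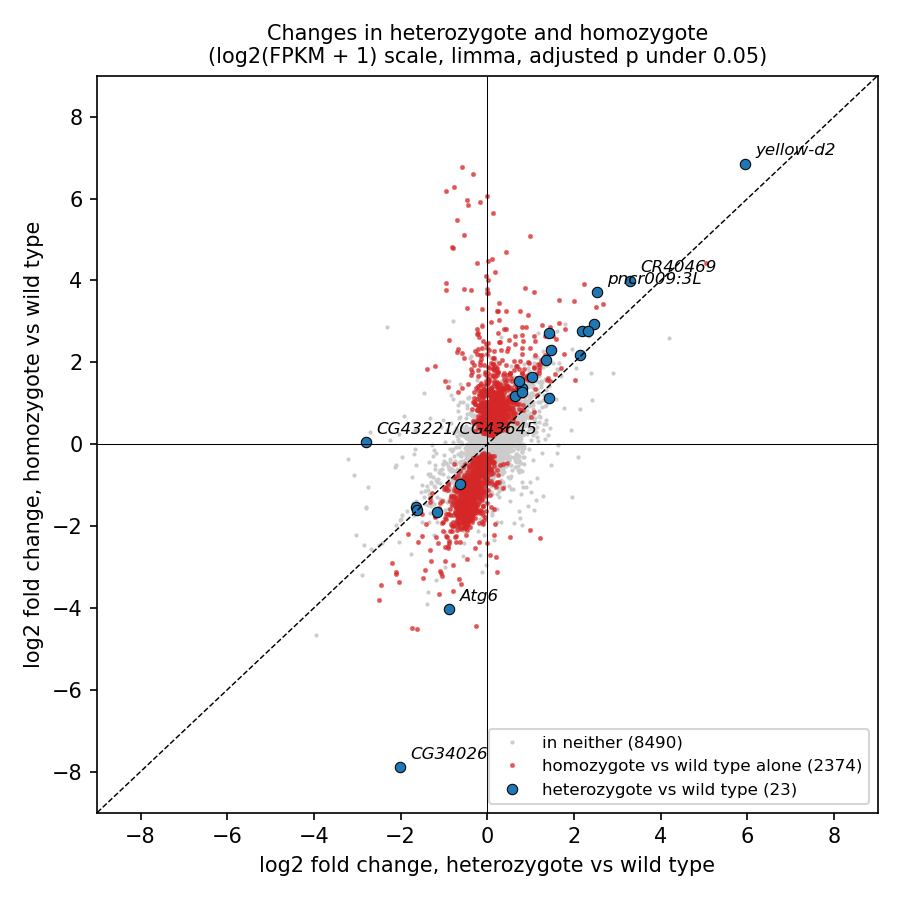
Log2 fold change against the wild type of each of 10887 genes in the heterozygote (horizontal) and the homozygote (vertical), from 3 libraries per genotype, with a dashed line of equal change. Grey points were past the threshold in neither, red (2374) in the homozygote alone and blue (23) in the heterozygote.

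In the heterozygote 0 genes of any list were past the limma threshold over all genes, while list medians ran from −1.68 to 0.61. By camera 14 of 42 lists passed (9 up and 5 down), with 0 by an estimated correlation (lowest adjusted p = 0.945) and 0 by fry. Ribosomal proteins leaned up (median 0.26, camera adjusted p = 9.58e-25, 26 higher and 0 lower at an unadjusted p under 0.05, as in RpL41), but after quantile normalization the median was −0.01 (adjusted p = 0.910). Antimicrobial peptides (median −1.68, adjusted p = 4.70e-06), proteasome genes (−0.26, adjusted p = 8.58e-06), heat shock genes (−0.64, adjusted p = 0.00120), testis genes (−0.39, adjusted p = 0.00275) and bomanins (−0.53, adjusted p = 0.0426) leaned down. Against each gene's mean, the antimicrobial median was −0.62, −0.74 and −1.44 in the heterozygotes. It was −1.01 in wild type 2, but 0.94 and 2.31 in wild types 1 and 3. Cell cycle (0.11, adjusted p = 0.00275), muscle (0.54, adjusted p = 0.00505), glycolysis (0.61, adjusted p = 0.0101) and oxidative phosphorylation (0.37, adjusted p = 0.0101) leaned up. So did lipid (0.23, adjusted p = 0.0102), digestive (0.36, adjusted p = 0.0103), cuticle (0.41, adjusted p = 0.0215) and P450 lists (0.30, adjusted p = 0.0315). Adjusted over a list alone, 4 digestive enzymes rose and 1 fell, 1 Imd and 1 Toll gene rose, and 1 P450, 1 Toll, 1 JAK/STAT and 1 ecdysteroid gene fell. The autophagy list (27 genes, median −0.01, camera adjusted p = 0.951), the endosome list (median −0.01, mean 0.00, adjusted p = 0.985) and the lamellocyte list (median 0.06, mean −0.05, adjusted p = 0.951) did not pass. Nor did the other 25 (adjusted p = 0.0628 to 0.951).

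Leaving out wild type 1, wild type 3, heterozygote 1, heterozygote 2, heterozygote 3 or homozygote 3 lowered the 23 heterozygote calls to 12, 9, 10, 9, 10 and 10, with a highest count of 27 without another library. The 14 lists became 6 without wild type 1 (5 of them among the 14) and 8 without heterozygote 1 (6 of them). Other lists were thus newly past the threshold in both cases. Testis, muscle, cuticle and lipid lists were lost without either library. Digestive, glycolysis, oxidative phosphorylation and P450 lists were lost without either or wild type 3, bomanins without wild type 1, wild type 3 or heterozygote 2, and the cell cycle list without wild type 2. Bomanin (adjusted p = 0.0853), digestive (0.167) and lipid lists (0.127) were lost after quantile normalization, bomanins also with a pseudocount of 5 (0.254) or no filter (0.233), and P450 genes with a filter at 5 FPKM (0.154).

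What the loss of the 2nd copy added was read from homozygote against heterozygote, again with 3 libraries each. Bomanin and daisho peptides separated these groups too. IM3 stood at 3.34 ± 1.7 and 706 ± 302 FPKM (log2 fold change 7.35, SE 0.51, limma adjusted p = 0.000260) and IM14 at 0.648 ± 0.62 and 200 ± 72 (6.94, SE 0.42, adjusted p = 0.000157). The lamellocyte integrin ItgalphaPS4 went from 0.664 ± 0.36 to 117.9 ± 12.53 FPKM (6.18, SE 0.39, adjusted p = 0.000185). Of 10887 genes 838 were past the threshold, 683 of them higher and 155 lower (303 at least 2-fold, and 2852 at an unadjusted p under 0.05). CG34026 fell again, by −5.87 (SE 0.18, adjusted p = 8.1e-06), and GstO3 by −2.63 (92.4 ± 1.4 to 14.2 ± 2.2 FPKM, SE 0.11, adjusted p = 3.59e-05).

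Bomanin and daisho genes rose in 12 of 14 cases, and 0 fell (13 and 0 alone; median 5.15, limma camera adjusted p = 2.29e-15, and adjusted p = 0.0960 with an estimated correlation). IM4 (7.13, SE 0.70), IM2 (7.03, SE 0.49), IM1 (6.28, SE 0.55) and CG16836 (BomT2; 5.65, SE 0.50) were among the 10 largest rises, with CR44948 (6.44, SE 0.62) and CG14610 (6.10, SE 0.56). Lamellocyte markers rose in 7 of 10 cases, and 0 fell (9 and 0 alone; median 1.18, adjusted p = 1.75e-09, and 0.0960 with an estimated correlation). CG1208/glob3 rose by 5.60 (SE 0.37) and mys by 1.55 (SE 0.11, adjusted p = 0.000260). Of 13 plasmatocyte markers 5 rose and 0 fell (5 and 1 alone; median 0.35, adjusted p = 0.0407, and 0.781 with an estimated correlation). Lowest in p were He (2.11, SE 0.17, adjusted p = 0.000497), Sr-CI (2.13, SE 0.25, adjusted p = 0.00235) and NimC1 (a phagocytosis receptor; 1.28, SE 0.20, adjusted p = 0.00942). The JNK list had 7 of 15 higher and 0 lower (10 and 0 alone; median 0.54, adjusted p = 1.60e-05, and 0.168 with an estimated correlation). The matrix protease Mmp1 rose (24.7 ± 1.2 to 69.4 ± 17 FPKM, 1.43, SE 0.19, adjusted p = 0.00446), as did kay (0.67, SE 0.09, adjusted p = 0.00334). Of JAK/STAT genes 6 rose and 1 fell (9 and 1 alone; adjusted p = 0.000174, and 0.0960 with an estimated correlation), led by TotB (3.99, SE 0.63, adjusted p = 0.00923). Of Imd genes 4 rose and 0 fell (6 and 0 alone; adjusted p = 0.000501, and 0.0965 with an estimated correlation), led by PGRP-LF (0.91, SE 0.10, adjusted p = 0.00198). Of Toll genes 4 rose and 0 fell (4 and 0 alone; adjusted p = 0.0482, and 0.719 with an estimated correlation), led by Tl (0.86, SE 0.08, adjusted p = 0.000921) and dl (0.93, SE 0.13, adjusted p = 0.00630). These genes kept their calls without each library. Drs rose (to 949 ± 546 FPKM, 5.18, SE 1.25, adjusted p = 0.0465), the 1 of 16 antimicrobial peptide genes to do so (0 alone; median 1.16, adjusted p = 0.0700, and from 0.0148 without wild type 2, wild type 3 or homozygote 3). It lost its call without wild type 3, any heterozygote or any homozygote (adjusted p up to 0.154).

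Other lists went in part as they had against the wild type. Of ribosomal proteins 13 rose and 0 fell (71 and 0 alone; median 0.39, limma camera adjusted p = 5.01e-17, and adjusted p = 0.719 with an estimated correlation). RpS9 went from 955 ± 32 to 1415 ± 103 FPKM (0.56, adjusted p = 0.0224, and up to 0.113 without a heterozygote). After quantile normalization 0 were past the threshold (10 higher and 1 lower at an unadjusted p under 0.05, median 0.21). Mitochondrial ribosomal proteins (3 rose, 0 fell, 0 and 0 alone; adjusted p = 8.73e-05, lost without homozygote 1) and endosome genes (4 rose, 0 fell, 10 and 0 alone; adjusted p = 9.47e-05, and 0.0733 after quantile normalization) leaned up. Apoptosis genes (3 rose, 0 fell, 7 and 0 alone; adjusted p = 0.00413) and glutathione transferases (3 rose, 0 fell, 3 and 0 alone; adjusted p = 0.0271), not past the threshold against the wild type (0.0651 and 0.264), did so too. With an estimated correlation these 4 lists had adjusted p = 0.248 to 0.781. GstD2 rose by 2.90 (SE 0.27, adjusted p = 0.000861) and GstE2 by 1.31 (SE 0.17, adjusted p = 0.00327). Testis (median −0.99, adjusted p = 5.66e-06, 13 lower at an unadjusted p under 0.05), ecdysteroid (−0.45, adjusted p = 0.0125, 7 lower alone) and glue lists (−2.14, adjusted p = 0.0172, 8 lower alone) leaned down. Imaginal disc (adjusted p = 0.0189, 5 lower unadjusted) and proteasome lists (−0.16, adjusted p = 0.0271, 5 lower unadjusted) did as well. In these 5 lists 0 genes were past the limma threshold, and adjusted p was 0.719 to 0.781 with an estimated correlation. Muscle (median 0.16, camera adjusted p = 0.476), oxidative phosphorylation (0.20, adjusted p = 0.411) and heat shock lists (−0.41, adjusted p = 0.312), past the threshold against the wild type, were not past it here, and glycolysis was at 0.05 (adjusted p = 0.632). Set calls were lost without homozygote 1 or 3 for glutathione transferases and imaginal disc genes, and without heterozygote 3 or homozygote 1 for the proteasome (adjusted p up to 0.758). They were lost without heterozygote 1 for glue, plasmatocyte and Toll lists, and for the last 2 also without homozygote 1 or 2, as for Toll without wild type 3 or heterozygote 2 (adjusted p up to 0.131). With a filter at 5 FPKM plasmatocyte, Toll, glutathione transferase and proteasome calls were lost (0.0813 to 0.234), after quantile normalization plasmatocyte, Toll and imaginal disc calls (0.12 to 0.31), and with a pseudocount of 5 that of Toll (0.0511). Of the 42 lists 17 passed by camera (12 up and 5 down), 0 with an estimated correlation and 9 by fry. Those that fry did not pass were the ecdysteroid and plasmatocyte (each fry adjusted p = 0.0654), glue (0.105), testis and imaginal disc (each 0.219), glutathione transferase (0.238), mitochondrial ribosomal (0.396) and proteasome lists (0.552). Among single genes, the protease Jon99Fi (3171 ± 217 to 412 ± 201 FPKM, −3.07, SE 0.36, adjusted p = 0.00241), the odorant-binding protein Obp56e (−2.80, SE 0.39, adjusted p = 0.00502) and CG4000 (−2.76, SE 0.35, adjusted p = 0.00326) fell and held without each library.

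Victoria (6.06, SE 1.00, limma adjusted p = 0.0110) and CG8665 (a folate dehydrogenase; −3.50, SE 0.60, adjusted p = 0.0133) lost their calls without heterozygote 2 or 3 (adjusted p = 0.0522 to 0.0619). CG18606 (AANATL6; −3.33, adjusted p = 0.0322), CG5866 (−2.70, adjusted p = 0.0420) and CG3292 (−2.56, adjusted p = 0.0378) fell. Their calls were lost without wild type 3, any heterozygote and 1 or more of wild type 1 and the 3 homozygotes (adjusted p up to 0.143). Leaving out wild type 3, heterozygote 1, 2 or 3, or homozygote 3 lowered the 838 calls to 556, 430, 303, 340 and 419, and the highest count without another library was 815. Of these calls other than Atg6, 26 lay within 1 Mb of Atg6 (odds ratio 1.47, 95% interval 0.931 to 2.22, Fisher exact p = 0.0852) and 88 within 5 Mb (odds ratio 1.32, 1.03 to 1.67, Fisher exact p = 0.0227).

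Whether the heterozygote lay midway between the other genotypes on the log scale was tested gene by gene. It departed from the midpoint for 109 of 10887 genes by limma (14 above it and 95 below it, with 994 at an unadjusted p under 0.05). The adenylate cyclase Ac78C was at 3.61, 2.60 and 14.6 FPKM in wild type, heterozygote and homozygote (−1.23 from the midpoint, adjusted p = 0.00162). RapGAP1, a GTPase activator, was at 10.8, 9.07 and 40.0 (−1.12, adjusted p = 0.00219), and IM3 at −3.97 from the midpoint (adjusted p = 0.00885). Above the midpoint were Atg6 (1.14, adjusted p = 0.00219) and CG34026 (1.93, adjusted p = 0.00281). Both were near 0 FPKM in the homozygote, which places a heterozygote in proportion to dose above a log midpoint. For Atg6 (15.8, 8.15 and 0.0278 FPKM) the result is therefore no departure from gene dose. Above the midpoint too was GstT3 (0.86, adjusted p = 0.00885), at 38.4 and 31.3 FPKM with 1 and 2 copies lost. Ac78C and RapGAP1 were chosen for their low p after the values were seen. A test of any difference among the 3 genotypes called 1158 genes, with 3554 at an unadjusted p under 0.05. Without wild type 1, wild type 3, heterozygote 1, heterozygote 2, heterozygote 3 or homozygote 3 the 109 became 68, 63, 13, 13, 27 and 61. Without wild type 1, wild type 3, heterozygote 2, heterozygote 3 or homozygote 3 the 1158 became 768, 543, 644, 692 and 490 (1267 at most).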

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

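Counts of called genes depended on which libraries were kept, on the threshold and on which genotypes shared a fit. Without 1 library at a time, limma called 726 to 3088 genes for homozygote against wild type, 9 to 27 for heterozygote against wild type, 303 to 815 for homozygote against heterozygote, 13 to 101 off the midpoint and 490 to 1267 between any genotypes, and lists numbered 13 to 18, 6 to 16 and 13 to 20. The genotype with a library left out had 2 libraries, which are assumed to vary like the others. With only the 2 genotypes compared in each fit, 693, 8 and 546 genes were called.

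The replicate numbers did not pair the libraries: of 9 same-numbered pairs 2 had a correlation over 0.1 (−0.647 to 0.331), and 3 of 18 best matches shared a number. With a block for that number, limma called 966, 9 and 437 genes, 15 off the midpoint and 502 between any genotypes, with 9 shared by homozygote and heterozygote. The muscle list of homozygote against wild type (adjusted p = 0.0515) and the plasmatocyte and Toll lists of homozygote against heterozygote (each 0.0798) were then not past the threshold.

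At an adjusted p under 0.01 the counts were 623, 9 and 306, with 28 off the midpoint and 388 between any genotypes. At least 2-fold were 1093 and 303 genes in the 2 homozygote comparisons, 53 off the midpoint and 475 between any genotypes. Library weights did not reach their tolerance and gave homozygote 3 a weight of 78.7 against 0.154 to 5.61 for the others, so their counts (8957, 2106, 7048, midpoint 2624, any genotype 9194) are not usable.

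With the muscle list score as a covariate, added after the data were seen, 36 genes and 7 lists were past the threshold in the heterozygote, 1937 genes in homozygote against heterozygote, 272 off the midpoint and 1888 between any genotypes. For homozygote against wild type it called 2097 genes, 1477 of them among the 2396, and 17 lists, 10 of them among the 16. Ecdysteroid (adjusted p = 0.0583), imaginal disc (0.206), muscle (0.760), oxidative phosphorylation (0.855), proteasome (0.0510) and glue lists (0.0671) were lost. Against the heterozygote 13 of 17 lists were kept, and glutathione transferase (0.0700), plasmatocyte (0.0601), proteasome (0.104) and glue lists (0.0580) were lost. The glycolysis gene Ald then changed sign in homozygote against wild type, to −0.56 (limma adjusted p = 0.0145) from 0.39, not past the threshold (the cause was not tested).

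With an estimated correlation 0, 0 and 0 lists passed in the 3 comparisons, against 16, 14 and 17. By fry 0 passed in the heterozygote and 9 in homozygote against heterozygote. The excess of heterozygote calls near Atg6 fell to an odds ratio of 1.73 within 5 Mb (Fisher exact p = 0.424) and 2.77 for genes at least 2-fold changed (p = 0.317).

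Pseudocounts, filters, trend, robust fit, scaling, repeated lines, Lsp1beta and single-name loci left each total within 1.5 times its value (for example 1771 to 2479 genes under the 2 scalings and 2428 with repeated lines, for homozygote against wild type). Its lower calls went from 1053 to 589 with a pseudocount of 5 and 659 with the stricter filter, those of the heterozygote from 7 to 0 with a pseudocount of 0.1, and higher calls of homozygote against heterozygote from 683 to 449 after quantile normalization. Of 2910 results for single named genes without 1 library, 2286 were on the same side of the threshold, 617 no longer past it and 7 newly past it; for 5149 under other settings these were 4546, 592 and 10, with Ald reversed. For lists they were 1034, 58 and 42 of 1134, and 1205, 127 and 54 of 1386.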

Other observations

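In addition to the planned lists, genes were grouped by name stem after the data were seen, and 99 families of at least 5 tested loci were compared with the other genes in homozygote against wild type by 1-sided Fisher exact tests (198 tests, adjusted together). These tests took genes as independent, whereas 0 planned lists passed in this comparison with an estimated correlation between genes. Ribosomal, heat shock, Mst, Rab and Vps families share genes with planned lists. Besides ribosomal proteins, translation initiation factors held more rises than other genes (12 of 28 higher and 4 lower, median log2 fold change 0.22, adjusted p = 0.00266), as in eIF-3p66 (104 ± 4.41 to 223 ± 15.0 FPKM, 1.09, SE 0.09). Their 4 falls included the germline forms eIF4E-3 (−1.47) and eIF4E-4 (−1.90). Of aminoacyl-tRNA synthetases 10 of 22 rose (median 0.32, adjusted p = 0.00420), led by Aats-tyr (44.9 ± 1.94 to 82.0 ± 1.73 FPKM, 0.86, SE 0.08). Quantile normalization kept both medians above 0 (0.06 and 0.32) but left 2 initiation factors higher and 3 lower and 5 synthetases higher, with no excess of rises (adjusted p = 1 and 0.994). The first excess was lost without wild type 1, wild type 3 or homozygote 3 (adjusted p up to 0.410), and the second without homozygote 2 (0.0655).

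By the same tests, which took genes as independent, some families of the cytoskeleton and membranes held an excess of rises as well. Of 6 subunits of the Arp2/3 actin-branching complex 5 rose (median 0.56, Fisher exact test adjusted p = 0.00432), with Arpc1 going from 116 ± 7.33 to 247 ± 43.4 FPKM (1.07, SE 0.15) and Arpc3B from 41.4 ± 6.27 to 94.5 ± 21.7 (1.16, SE 0.19). Tetraspanins changed in both directions (11 of 26 higher and 2 lower, median 0.29, adjusted p = 0.00420): the locus Tsp42Eb/Tsp42Ec rose from 54.9 ± 13.2 to 215 ± 38.6 FPKM (1.96, SE 0.20), and Tsp42Ep fell from 87.1 ± 8.26 to 21.7 ± 15.8 (−2.41, SE 0.69). Of Rab GTPases 9 of 23 rose (median 0.27, adjusted p = 0.0258) and of Vps sorting proteins 7 of 16 (median 0.30, adjusted p = 0.0352), as in Rab9 (0.72, SE 0.10), Rab35 (0.53, SE 0.07) and the ESCRT subunit Vps36 (0.49, SE 0.07). Heat shock proteins fell (8 of 12, median −1.67, adjusted p = 0.000171), in part through germline chaperonins such as Hsp60B (−1.86, SE 0.54), as did the Mst sperm protein genes (6 of 14, median −1.68, adjusted p = 0.0269). Medians of these 6 families kept their sign under both scalings, though median-of-ratios scaling changed the values little. After quantile normalization 4 Arp2/3, 6 tetraspanin, 3 Rab and 2 Vps genes were called higher, with no excess (adjusted p = 0.0773, 0.901, 1 and 1), and 6 heat shock and 6 Mst genes lower (adjusted p = 0.00935 and 0.0136). Median-of-ratios scaling ended the Vps excess (0.0509). The Arp2/3 excess was lost without wild type 3 (0.109), and that of tetraspanins without any of the 9 libraries (up to 0.782). Those of Rab, Vps, heat shock and Mst genes were lost without 8, 7, 7 and 7 of the 9 (up to 1): Rab held without homozygote 1, Vps without heterozygote 3 or homozygote 1, and the other 2 without wild type 2 or homozygote 1.

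The tests of 3 patterns below were chosen after the results were seen, and 4 of them replaced an earlier test whose outcome was known; splits of the libraries were set before. Of the 10 ways to split 6 libraries into 3 and 3, 1 (the real one) gave as many calls in each comparison: 2396 for homozygote against wild type (highest other 712), 23 for heterozygote against wild type (1) and 838 for homozygote against heterozygote (1), and 10 splits are too few for a share under 0.05. Of 100 splits into 3 groups, 3 gave at least 1158 genes between any groups (highest other 1244), where both others kept the 3 homozygotes together and the highest count with them apart was 325. For the midpoint 2 of 100 reached 109 (highest other 1524, from a split with the homozygotes as the middle group, and 12 with them apart).

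Testis genes were lower in the homozygote (list mean −1.17, 95% interval −2.12 to −0.21). Fewer males among these larvae could not be told apart. The male RNAs roX1 and roX2 had a mean of −0.06 (95% interval −0.775 to 0.659). A fall of these RNAs as large as the testis median of −1.43 lay outside that interval. The interval of the testis mean overlapped it, however, and the difference between testis genes and these RNAs was not tested. The Y-linked RNA Su(Ste):CR42422 was higher in the homozygote (1.22 ± 0.36 to 8.25 ± 1.36 FPKM, 2.06, limma adjusted p = 0.000313). As 1 weakly expressed gene, open to variants of the stock, it does not settle the share of males. Wild type 1 had the highest testis values, but without it the median was still −0.952. A difference in stage could not be told apart: earlier readings of the glue scores of single libraries, lowest in homozygote 1 (−3.47), and of the glue score as a covariate (mean −2.02, upper end −0.859, and −1.67 to −0.435 without 1 library) decide nothing, as homozygote 1 held 55.4% of the spread of that score within genotypes and the score itself was lower in the homozygotes. Smaller or later testes in the homozygote remain a candidate that these data could not test.

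Atg6 dose and variants that came with the mutant stock could each underlie the 23 heterozygote calls. Variants linked to Atg6 would sit with its neighbours on chromosome 3, but variants elsewhere in the stock could sit on any chromosome. Of the calls, 11 lay on the X (odds ratio 4.83, Fisher exact adjusted p = 0.00322), 3 on chromosome 2 and 1, Su(Ste):CR42422, on the Y. Of the 22 calls other than Atg6, 3 lay within 1 Mb of it (odds ratio 7.05, lower 95% bound 1.33), but within 5 Mb the excess was not past its interval (odds ratio 1.73, 95% interval 0.328 to 5.9), while calls of homozygote against heterozygote held an excess within 5 Mb (odds ratio 1.32, 1.03 to 1.67) and not within 1 Mb (1.47, 0.931 to 2.22); an earlier test on the X and that 1 Mb together (odds ratio 7.89) joined regions picked from the same calls and decides nothing, so the stock cannot be told apart from dose. Some calls were about as high in the heterozygote as in the homozygote, GstT3 on the X (1.43 and 1.14) and CG31226 further from Atg6 (2.14 and 2.18). On the X, CG42578 went from a mean of 2.13 FPKM to 0 in the 3 heterozygotes (−1.64, and −1.54 in the homozygote). There too, snoRNA:Psi28S-1135a went from 2.09 FPKM to 0 in each heterozygote and homozygote. Both were weakly expressed. Of the 23 calls, 10 were not past the limma threshold between homozygote and heterozygote, and 13 were, of which 12 lay further from the wild type in the homozygote. Chance values of the shared wild types could not be told apart as a cause of the 23 calls. Of 100 simulations of an unchanged heterozygote 97 had 0 calls and 3 had at least 23, with 4112 and 2874 the highest. Counts that uneven do not show how often about 23 calls would arise. That test replaced an earlier one, the highest number of shared calls in any simulation (337 against 22 observed), which would have left the cause standing. An effect of Atg6 dose on these genes was not tested.

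Bomanin and lamellocyte genes rose together in the homozygote. More blood cells of each kind could not be told apart. The lamellocyte mean exceeded that of plasmatocyte and crystal cell lists by 1.38 (lower end of the 95% interval 0.988). In RNA of whole larvae, markers also made by other tissues would rise less, so the lists need not rise equally. A single unusual library is an unlikely cause, since the bomanin median was at least 4.21 without any 1 homozygote. A systemic infection could not be told apart: the interval of Drs reached 6.34 (−0.62 to 6.34, mean 2.86), whereas an earlier test on the antimicrobial peptide list (mean −0.38, −2.51 to 1.76, against 4.36, 3.62 to 5.11, for bomanins) would have excluded it, and was replaced because these peptides were high in wild types 1 and 3. Listericin, a gene of that list, had a lower mean (−1.14, −2.20 to −0.07 without adjustment), but no gene of the list was past the limma threshold. The bomanins exceeded the antimicrobial peptides by 4.74 (3.05 to 6.43).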
